A study of Mus musculus with 9 samples.

How the data were processed

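Total RNA from NIH 3T3 cells with a control vector, a Net shRNA or a Sap-1 shRNA was hybridised to 9 Affymetrix Mouse Gene 1.0 ST arrays, 3 per group, 1 per biological replicate. The deposited table holds 1 log2 level per probe set and array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version or settings. RMA subtracts background, brings the arrays to a common distribution and summarises the probes of a probe set on the log2 scale, so small folds of dim genes are compressed and a change shared by most genes would be removed. The values ran from 3.24 to 14.47 over the 28815 probe sets, with medians of 7.47 to 7.54 per array. The table holds no detection calls, so no probe set was called absent. Array values have no read depth, and the number of arrays limits the precision.

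Probe sets were named through the platform annotation, with symbols brought up to date through Entrez IDs in a RefSeq gene table of assembly GRCm38.p6, which held the IDs of 21689 probe sets. A single symbol was given for 21780 probe sets, several for 1605 and none for 5430, and genes were named from the first kind only. Genes found only on the other kinds were not analysed here. For the 998 genes with more than 1 probe set the one with the highest mean over all arrays was used, which left 19935 genes. Called probe sets of a gene opposed each other for Dlc1 and Zmpste24 in Net shRNA cells, for Fut11 in Sap-1 shRNA cells, and for Dlc1, Dnah3, Fut11, Prkg2 and the mitosis gene Top2a between the knockdowns. The genome build of the array's design was not given, so the RefSeq table served for names and the order of neighbouring genes only. Named genes known to belong to families of close copies, namely Prl2c5, Aldh1a7, Serpinb9b, Usp17la and Lyz2, are described as uncertain. Other named genes may have close relatives as well, cross-hybridisation was not tested, and 26 tested genes had values identical to those of another probe set.

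Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend) in 1 fit over all 9 arrays with a mean per group, 6 residual degrees of freedom and 4.7 prior ones, and Benjamini-Hochberg adjustment over the 19935 genes of each of the 3 comparisons. A gene was called at an adjusted p under 0.05. Replicates are given as mean ± SD, and the error of a fold change is the standard error of the fit. The 21 gene lists, the design, the other settings and the rule for naming genes were fixed before the data were examined. Named were the ternary complex factor genes and a few known SRF targets, the 8 largest rises and falls of each comparison among called genes whose groups did not overlap (predicted genes, small RNA genes and olfactory and vomeronasal receptor genes passed over), up to 4 called members per list with the smallest adjusted p, and up to 5 genes per direction for the overlap. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes.

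The other settings were the replicate number as a block, an intensity trend with robust variances, only the 6 arrays compared, 3 other normalizations, 2 filters on dim probe sets, the mean of a gene's probe sets, every probe set, array weights, each array left out, a threshold of 1.5-fold and an adjusted p under 0.01. One was added after seeing the data, in which the median deviation of each gene's 50 nearest expressed neighbours was taken off in every array. The scan of neighbouring genes used windows of 50 genes in steps of 10 and 1000 random gene orders. The overlap of both knockdowns was set against 100 simulated sets of unchanged groups drawn from the residuals of the fit.

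The scripts were tested on simulated data with the same 19935 genes and 9 arrays. Of 50 genes changed at each size in the simulated Net comparison, 2% were called at 1.1-fold, 70% at 1.2-fold, 98% at 1.5-fold and 100% at 2-fold, with 12 false calls. The simulated Sap-1 comparison, which held no change, gave 0 false calls with limma. The list test called 1 of 21 lists, the one that had been raised. Simulated genes varied independently of each other, whereas the estimated correlation within the real lists ran from 0.017 to 0.497. The simulation therefore does not check the list test on correlated genes.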

Results

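Messenger RNA was measured in NIH 3T3 cells, a mouse fibroblast line, that stably carried the empty pLKO.1 lentiviral vector, an shRNA against Net or an shRNA against Sap-1. Net (gene Elk3) and Sap-1 (gene Elk4) form with Elk-1 (gene Elk1) the ternary complex factors, ETS-domain proteins that bind DNA together with serum response factor and are phosphorylated by MAP kinases. Cells attached to fibronectin for 2 hours, were kept overnight in medium free of serum and received bovine serum for 1 hour before lysis. The labels give the serum as 10% in the sample protocols and as 20% in the series description, so its concentration stays open. Each of the 3 groups held 3 biological replicates, 1 array each, and every array was taken after serum, so the serum response itself was not measured. The 9 arrays had medians of 7.47 to 7.54 on the log2 scale, and the number of arrays limits the precision. Arrays of a group correlated at 0.9981 to 0.9992 across probe sets and arrays of different groups at 0.9879 to 0.9947. The first principal component, 57.9% of the variance, set the Sap-1 shRNA arrays apart, and the second, 29.2%, separated Net shRNA from control.

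The targeted genes were examined first. Elk4 fell by 1.54 on the log2 scale in the Sap-1 shRNA cells (SE 0.04, limma adjusted p = 9.2e-10), from 11.07 ± 0.05 to 9.53 ± 0.02 (SD, n = 3 arrays each), a level 65.5% lower than control. Elk3 fell by 0.42 in the Net shRNA cells (SE 0.04, limma adjusted p = 1.1e-05), from 11.51 ± 0.02 to 11.08 ± 0.02, a level 25.5% lower. Elk4 also fell in the Net shRNA cells, by 0.44 (SE 0.04, adjusted p = 2.3e-05), and it fell by 0.28 with the median of its neighbouring genes taken off, though 5 of its 50 neighbours fell further than Elk4 itself. That fall was as large as the fall of Elk3 itself, so the Net shRNA arrays do not separate the 2 factors at the level of mRNA. Elk3 fell by 0.12 in the Sap-1 shRNA cells (adjusted p = 0.023), a call that was lost when each array was centred on its median (-0.10, adjusted p = 0.12). Elk1 passed the test in neither line, at 0.02 in Net shRNA and -0.08 in Sap-1 shRNA cells (adjusted p = 0.85 and 0.27).

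**Figure D1:**
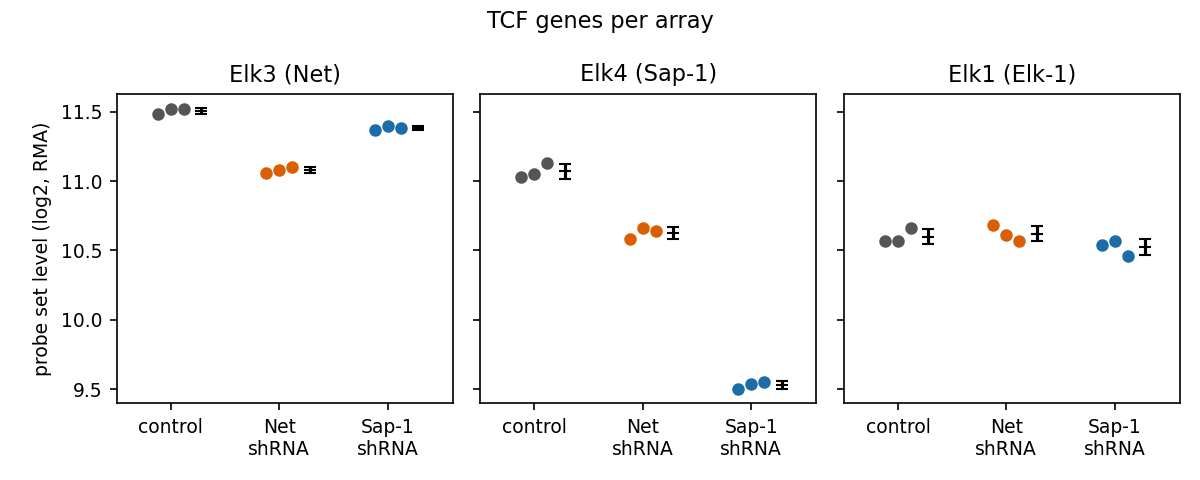
Probe set levels (log2, RMA) of Elk3, Elk4 and Elk1 in the 3 control, 3 Net shRNA and 3 Sap-1 shRNA arrays, each point an array, with the group mean and SD beside the points. Elk4 drops from 11.07 to 9.53 in Sap-1 shRNA cells, Elk3 from 11.51 to 11.08 in Net shRNA cells, and Elk4 lies at 10.63 in Net shRNA cells.

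The comparison of Net shRNA with control asks which transcripts differ in serum-treated fibroblasts that carry the Net shRNA. In these cells both Elk3 and Elk4 mRNA were lower, and protein was not measured. Rtl3, a gene derived from a retrotransposon, rose most, by 4.92 on the log2 scale (SE 0.09, limma adjusted p = 2.2e-10), from 6.07 ± 0.19 to 11 ± 0.08 (SD, n = 3). Among the next largest rises were those of P2ry10b (3.55, SE 0.1), the lysophosphatidic acid receptor gene Lpar4 (3.37, SE 0.08) and the ephrin receptor gene Epha7 (3.01, SE 0.05). Wfdc18, Ms4a4d, Srpx2 and the tight junction gene Cldn1 rose by 2.58 to 2.97. Mest, an imprinted gene, fell most, with a change of -3.08 (SE 0.15, adjusted p = 1.7e-07), followed by the laminin gene Lama2 (fell by 2.59, SE 0.07) and Simc1 (fell by 2.24, SE 0.05). The sodium pump subunit gene Atp1b1 (-2.20), the matrix gene Dpt (-1.98) and the receptor phosphatase gene Ptprm (-1.87) fell as well. Prl2c5 fell by 2.23 and Phxr4 by 2.14 (SE 0.27), and Prl2c5 is uncertain because its family holds near-identical copies.

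Cell cycle genes had many more members higher than lower in Net shRNA cells. Of 38 measured DNA replication and S phase genes, 26 rose and 1 fell, among them Cdt1 (0.65), Cdc6 (0.60), Rrm2 (0.54) and Tyms (0.51), all with SE 0.05. Of 34 mitosis genes, 23 rose and none fell, led by Aurkb (0.51, SE 0.05), Birc5 (0.48, SE 0.06) and Spc25 (0.44, SE 0.06). For comparison, 13.4% of all genes tested rose and 10.2% fell, dim genes included. Both lists were brighter than most genes, with list medians of 9.56 and 10.29 in control. With probe sets below the median left out, 2701 genes rose and 2117 fell out of fewer tested, so the shares among brighter genes were larger. The camera test with a preset correlation of 0.01 shifted both lists upward (adjusted p = 7.5e-13 and 1.1e-10), with adjusted p = 0.26 and 0.38 with an estimated correlation. Of 20 G1 cyclins and CDK inhibitors, 6 rose, among them Rb1 (0.76), Ccne2 (0.70) and Ccne1 (0.33), and only the cyclin D1 gene Ccnd1 fell, by 0.23 (SE 0.04, adjusted p = 0.0016), while the list as a whole did not pass (camera adjusted p = 0.06).

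Of 31 interferon-stimulated genes, 17 rose, none fell and 14 did not pass. Ifit1 rose by 2.01 (SE 0.08, limma adjusted p = 2e-08), Oasl2 by 1.00 (SE 0.08), Trim30a by 0.82 (SE 0.05) and Ddx58, the gene of the RNA sensor RIG-I, by 0.74 (SE 0.05). The list passed camera (adjusted p = 9.8e-09) but not with an estimated correlation (adjusted p = 0.22). Of 23 p53 target genes, 14 rose and 1 fell (camera adjusted p = 1.2e-08, and adjusted p = 0.26 with an estimated correlation), with Perp up by 2.27 (SE 0.13), Eda2r by 1.34 (SE 0.09) and Ckap2 by 0.89 (SE 0.07). Of the 26 genes fixed for that list, Cdkn1a, Bax and Gdf15 were not among those measured. Of 32 hypoxia and glycolysis genes, 14 rose and 1 fell (camera adjusted p = 1.4e-05, and adjusted p = 0.26 with an estimated correlation), led by the peptide hormone gene Adm (0.96, SE 0.04) and the haem oxygenase gene Hmox1 (0.78, SE 0.06). Cytoskeletal targets of the SRF coactivators MRTF went the other way, with 9 of 31 lower and 1 higher (camera adjusted p = 0.0027, and adjusted p = 0.48 with an estimated correlation). In this group the myosin light chain gene Myl9 fell by 0.43 (SE 0.06), Mical2 and Jak2 by 0.34 each (SE 0.05) and the integrin gene Itga5 by 0.33 (SE 0.05).

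Immediate early and early serum response genes did not shift as a list in Net shRNA cells (8 of 36 higher, 3 lower, camera adjusted p = 0.59). Nr4a3 rose by 1.39 (SE 0.09) and Nr4a2 by 0.82 (SE 0.05), whereas Klf4 fell by 0.40 and Fosb by 0.37. Egr1 lay at -0.08 (adjusted p = 0.26), Fos at 0.15 (adjusted p = 0.26), Srf at 0.01 and Mcl1 at 0.01. Junb rose by 0.18 (SE 0.04, adjusted p = 0.0065), but its fold was -0.01 with the median of its neighbouring genes taken off. ERK feedback genes went both ways (6 of 22 higher, 4 lower, camera adjusted p = 0.75), with Lif up by 1.19, Spry1 by 0.46 and Dusp6 by 0.34. Inflammatory and NF-kB genes also went both ways (9 of 29 higher, 4 lower, adjusted p = 0.48), the chemokine genes Cxcl5 (1.58), Ccl5 (1.27) and Ccl7 (1.08) rising and the NF-kB inhibitor gene Tnfaip3 falling by 1.11. Extracellular matrix genes (7 of 41 higher, 9 lower, adjusted p = 0.75) included rises of the collagen IV genes Col4a1 (0.80) and Col4a2 (0.66) and a fall of Thbs2 by 0.72.

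In the other lists in Net shRNA cells the counts were 6 higher and 8 lower of 24 YAP-TEAD targets, 7 and 7 of 31 integrin and focal adhesion genes, 2 and 2 of 25 sterol synthesis genes, 6 and 7 of 33 stress response genes and 4 and 4 of 17 ETS factors. None of these 5 lists passed camera (adjusted p = 0.61 to 0.9). Among them Vldlr, a lipoprotein receptor gene, fell by 1.51 (SE 0.06), Itga1 rose by 0.95 and the ETS factor gene Fli1 by 0.73. Markers of other cell types stood low, with list medians of 6.55 to 7.16 in control. Endothelial markers were shifted upward by camera (3 of 15 higher, adjusted p = 0.039), a call lost with an estimated correlation (adjusted p = 0.26) and with probe sets below the median level left out (adjusted p = 0.28), and Tek, an angiopoietin receptor gene, rose by 1.84 (SE 0.05). Macrophage (3 of 15 higher), epithelial (2 of 14 higher), adipocyte (2 higher and 2 lower of 13) and skeletal muscle markers (2 of 15 higher) did not shift as lists (adjusted p = 0.7 to 0.94).

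In total 4714 of 19935 genes tested differed between Net shRNA and control cells, 2680 higher and 2034 lower, with a median change of 0.28 on the log2 scale among them. A change of at least 1.5-fold was reached by 510 genes, 317 higher and 193 lower. The arrays of both groups did not overlap for 34.3% of genes, where chance gives 10%. The balance was 2693 higher and 2585 lower with the neighbours' median taken off. The labels do not say how many stably transduced lines each group holds, and if each holds 1, p measures the spread within lines and does not cover differences between independently made lines.

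The comparison of Sap-1 shRNA with control asks the same question for the Sap-1 shRNA. Aldh1a7, an aldehyde dehydrogenase gene with a close paralog and therefore uncertain, rose by 3.73 (SE 0.07, limma adjusted p = 1e-10) and the phosphatase gene Ppef1 by 3.68 (SE 0.05). The protocadherin gene Pcdh9 rose by 3.54 (SE 0.07), the F-box gene Fbxl7 by 3.25, Gpr149 by 3.22, the transcription factor gene Foxp2 by 3.10 (SE 0.08) and Gpr39 by 3.06. Serpinb9b, a member of a family of close copies and uncertain, rose by 3.14. Lum, which encodes the collagen-binding proteoglycan lumican, fell most, with a change of -4.82 (SE 0.15, adjusted p = 2.2e-09), from 10.83 ± 0.14 to 6.01 ± 0.38 (SD, n = 3). Other large falls were those of AW551984 (-4.61, SE 0.06), Galnt17 (-3.67), Golm2 (-3.57), the growth factor gene Igf2 (-3.40, SE 0.27), Mest (-3.19, SE 0.15), the latrophilin gene Adgrl3 (-3.07) and the prostaglandin receptor gene Ptgfr (-2.67).

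Hypoxia and glycolysis genes had 26 of 32 members higher in Sap-1 shRNA cells, none lower and a list median of 0.44. Ero1a, a gene of oxidative protein folding, rose by 1.64 (SE 0.06, adjusted p = 7.7e-09), the prolyl hydroxylase gene Egln3 by 1.56 (SE 0.06), and the phosphofructokinase genes Pfkp and Pfkl by 1.41 (SE 0.06) and 1.15 (SE 0.04). The camera test gave adjusted p = 8.9e-17, and adjusted p = 0.081 with an estimated correlation. DNA replication and S phase genes rose in 30 of 38 members with none lower, among them Ccne2 (1.13, SE 0.09), Mcm3 (0.79, SE 0.05), Cdc6 (0.69) and Cdt1 (0.69). Mitosis genes rose in 15 of 34 members and fell in 3, with Racgap1 up by 0.43 and Prc1 by 0.38. Both lists passed camera (adjusted p = 2.1e-14 and 0.00021) and neither did with an estimated correlation (adjusted p = 0.27 and 0.57). Ccnd1 rose by 0.78 (SE 0.04, adjusted p = 9.8e-08) and the CDK inhibitor gene Cdkn2c fell by 0.49, in a list of 20 G1 cyclins and CDK inhibitors that had 8 higher and 2 lower members (camera adjusted p = 0.078).

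Stress response and p53 genes had more members higher than lower in Sap-1 shRNA cells. Of 33 integrated stress and ER stress genes, 17 rose and 2 fell (camera adjusted p = 3.3e-06, and adjusted p = 0.4 with an estimated correlation), with Sdf2l1 up by 1.19 (SE 0.05), Vldlr by 1.03 (SE 0.06) and Stc2 by 0.71. Of 23 p53 target genes, 15 rose and 2 fell (camera adjusted p = 7.4e-06, and adjusted p = 0.38 with an estimated correlation), led by Eda2r (1.69, SE 0.09) and Gtse1 (0.91, SE 0.08).

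Inflammatory, matrix and sterol genes had more members lower than higher. Of 29 inflammatory and NF-kB genes, 13 fell and 2 rose (camera adjusted p = 3.1e-05, and adjusted p = 0.081 with an estimated correlation), among them Ccl2 (-1.25), Cxcl12 (-1.21), Ccl7 (-1.12) and the adhesion molecule gene Vcam1 (-0.95), with SE of 0.04 to 0.06. Of 41 extracellular matrix genes, 18 fell and 8 rose (camera adjusted p = 0.0087, and adjusted p = 0.54 with an estimated correlation), and besides Lum the largest of the named falls were those of the periostin gene Postn (fell by 2.58, SE 0.06), Col12a1 (fell by 2.08, SE 0.08) and Thbs2 (fell by 1.12, SE 0.04). Of 25 sterol synthesis genes, 13 fell and 1 rose (camera adjusted p = 0.00028, and adjusted p = 0.43 with an estimated correlation), among them Dhcr7 (fell by 0.35), Mvk (fell by 0.31) and Lss (fell by 0.29). Hsd17b7 fell by 0.47 but lay at -0.11 with its neighbours' median taken off. Interferon-stimulated genes had 9 of 31 lower and 4 higher members, with Stat2 down (fell by 0.78), Ifit1 down (fell by 0.61) and Ifit2 up by 0.65. That list passed camera (adjusted p = 0.041) but not with an estimated correlation (adjusted p = 0.52), after cyclic loess (adjusted p = 0.061) or with the neighbours' median taken off (adjusted p = 0.16).

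Immediate early and early serum response genes fell in 14 of 36 members and rose in 3 in Sap-1 shRNA cells (camera adjusted p = 0.00065, and adjusted p = 0.43 with an estimated correlation). Arc fell by 0.98 (SE 0.06, adjusted p = 2.8e-07), Egr4 by 0.95 (SE 0.08), Mcl1 by 0.27 (SE 0.04, adjusted p = 0.00044) and Srf by 0.19 (SE 0.05, adjusted p = 0.0085). Nr4a2 rose by 1.03 (SE 0.05) and the phosphatase gene Dusp1 by 0.55 (SE 0.04). Egr1 lay at -0.09 (adjusted p = 0.17), Junb at -0.05 (adjusted p = 0.45) and Fos at -0.24 (SE 0.09, adjusted p = 0.06). Each of these 3 genes passed with the neighbours' median taken off, Egr1 at -0.15, Junb at -0.13 and Fos at -0.31, and Fos also passed after cyclic loess (-0.26, adjusted p = 0.036).

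The remaining lists did not shift in Sap-1 shRNA cells (camera adjusted p = 0.3 to 0.92). Their counts were 7 higher and 6 lower of 22 ERK feedback genes, 4 and 8 of 31 MRTF-SRF cytoskeletal genes, 10 and 6 of 24 YAP-TEAD targets, 7 and 6 of 31 integrin and focal adhesion genes and 4 and 6 of 17 ETS factors. Spry1 fell by 0.81 (SE 0.05) and Etv1 by 0.47, while the smooth muscle actin gene Actg2 rose by 1.32 (SE 0.07), Tes by 1.06 and Wwc1 by 0.83. Of the markers of other cell types, 4 of 15 macrophage, 1 of 14 epithelial, 3 of 15 endothelial, 2 of 13 adipocyte and 2 of 15 skeletal muscle genes were higher, and 1, 0, 1, 2 and 1 were lower. The lysozyme gene Lyz2, uncertain because of a close paralog, rose by 1.81 (SE 0.14), from 6.04 to 7.85, while Cd68 fell by 0.23.

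In total 5921 genes differed between Sap-1 shRNA and control cells, 3149 higher (15.8% of those tested) and 2772 lower (13.9%), with a median change of 0.30 among them. With the neighbours' median taken off the balance turned, to 3265 higher and 3576 lower, and with each array centred on its median it was 3354 higher and 2260 lower. At least 1.5-fold was reached by 890 genes, 462 higher and 428 lower, and arrays of both groups did not overlap for 41% of genes. Adjusted over the list alone, the members higher and lower were 27 and 0 for hypoxia and glycolysis, 33 and 0 for DNA replication, 3 and 18 for immediate early genes, 8 and 18 for extracellular matrix and 2 and 14 for inflammatory genes in Sap-1 shRNA cells. In Net shRNA cells, adjusted over the list alone, they were 29 and 1 for DNA replication, 28 and 0 for mitosis, 17 and 0 for interferon, 16 and 1 for p53 and 1 and 10 for MRTF-SRF genes. With an estimated correlation no list passed camera in any of the 3 comparisons, where 3 lists in each had an unadjusted p under 0.05, and fry called 9 lists in Net shRNA cells, 15 in Sap-1 shRNA cells and 12 between the knockdowns.

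**Figure D2:**
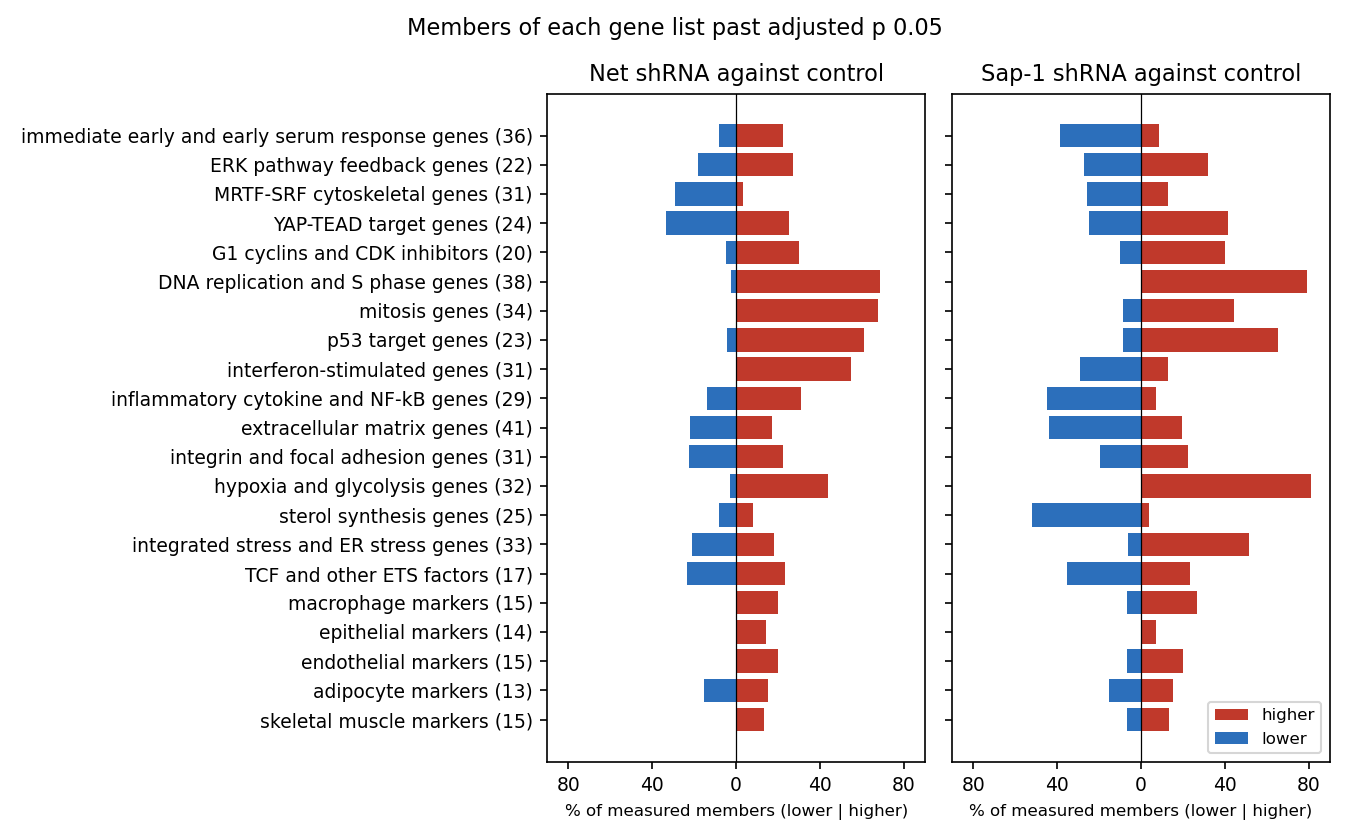
Percent of the measured members of each of 21 gene lists that were higher (right, red) or lower (left, blue) at a limma adjusted p under 0.05 in Net shRNA and in Sap-1 shRNA cells against control, with the number of measured members in brackets. DNA replication genes extend to the right in both panels (26 and 30 of 38), interferon-stimulated genes in the Net shRNA panel (17 of 31) and hypoxia and glycolysis genes in the Sap-1 shRNA panel (26 of 32).

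The direct comparison of both knockdowns tests where Net and Sap-1 shRNA cells differ from each other. Lum was higher in Net than in Sap-1 shRNA cells by 4.51 (SE 0.15, limma adjusted p = 2.8e-09), the angiotensin receptor gene Agtr2 by 4.36 (SE 0.09), AW551984 by 4.35, the Wnt modulator gene Sfrp2 by 4.33 (SE 0.09), Rtl3 by 4.16, Igf2 by 4.12 (SE 0.27), Golm2 by 3.77 and P2ry10b by 3.64. The semaphorin gene Sema3c was lower in Net shRNA cells, at -4.33 (SE 0.12, adjusted p = 4.7e-10), as were the carbonic anhydrase gene Car6 (-4.14, SE 0.05), Serpinb9b (-3.78), Cdsn (-3.63), Arhgap20 (-3.22), Foxp2 (-3.11), the Wnt agonist gene Rspo3 (-3.06) and Cdh19 (-2.91). Ccnd1 was lower in Net shRNA cells, at -1.01 (SE 0.04, adjusted p = 1.1e-08).

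Interferon-stimulated genes were higher in Net than in Sap-1 shRNA cells in 19 of 31 members and lower in 3, with Ifit1 at 2.61 (SE 0.08) and Ddx58 at 1.28 (SE 0.05). Inflammatory genes were higher in 14 of 29 and lower in 3, with Ccl7 at 2.19, Ccl2 at 2.09 and Cxcl5 at 1.97. Hypoxia and glycolysis genes were lower in 22 of 32 and higher in 3, with Ero1a at -1.44 and Bnip3 at -1.31, and stress response genes lower in 19 of 33 and higher in 3, with Vldlr at -2.54. Immediate early genes were higher in 19 of 36 and lower in 3, with Arc at 1.38, Egr4 at 1.24 and Fos at 0.39 (adjusted p = 0.005). Extracellular matrix genes were higher in 17 of 41 and lower in 6, with Col12a1 at 1.72, and sterol synthesis genes higher in 12 of 25 and lower in 1. These 7 lists passed camera (adjusted p = 1.4e-08, 8.4e-06, 1.4e-10, 2.7e-07, 2e-04, 0.0053 and 0.01 in the order given) and had adjusted p = 0.11, 0.11, 0.11, 0.39, 0.42, 0.76 and 0.76 with an estimated correlation. The sterol list was lost with the neighbours' median taken off (adjusted p = 0.14), and so were the single calls of Junb, whose fold went from 0.23 to 0.12 (adjusted p = 0.068), and Mcl1, from 0.28 to 0.10 (adjusted p = 0.097).

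DNA replication genes did not differ as a list between the knockdowns (5 of 38 higher and 11 lower in Net shRNA cells, camera adjusted p = 0.2), nor did mitosis genes (13 of 34 higher, 2 lower, adjusted p = 0.064, passing after cyclic loess with adjusted p = 0.031) or p53 targets (8 higher and 8 lower of 23, adjusted p = 0.72). MRTF-SRF cytoskeletal genes were lower in 11 of 31 and higher in 4 (adjusted p = 0.064), with Actg2 at -1.58. The other 10 lists did not shift (adjusted p = 0.2 to 0.86). In total 5480 genes differed, 2823 higher and 2657 lower in Net shRNA cells, and 924 of them by at least 1.5-fold. The balance turned to 2352 higher and 2819 lower with each array centred on its median, a setting that moves all genes of an array alike.

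Many genes changed the same way in both knockdowns. Epha7 rose by 3.01 in Net and 2.69 in Sap-1 shRNA cells, Agmo by 2.40 and 2.36, Usp17la (a member of a family of close copies and uncertain) by 2.28 and 2.85, the superoxide dismutase gene Sod3 by 2.13 and 2.40 and Pcdh9 by 2.07 and 3.54. Mest (-3.08 and -3.19), Atp1b1 (-2.20 and -2.19), the bombesin-like peptide receptor gene Grpr (-1.80 and -2.14) and the integrin ligand gene Npnt (-1.83 and -1.70) fell in both. Of the DNA replication genes 23 of 38 were higher in both, of the hypoxia and glycolysis genes 13 of 32 and of the p53 targets 11 of 23. Other genes went opposite ways: Sfrp2 (1.90 in Net, -2.43 in Sap-1 shRNA cells), Agtr2 (1.71 and -2.65) and Ccl7 (1.08 and -1.12) against Car6 (-1.66 and 2.48), Cdsn (-1.50 and 2.13) and Sema3c (-1.41 and 2.92). In all, 2377 genes were called in the same direction (1387 higher and 990 lower in both, where independent lists of these sizes would share 423 and 283) and 589 in opposite directions (310 and 279, where independent lists would share 373 and 321).

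Both comparisons share the 3 control arrays, too few to be split between them. In 100 simulated sets of unchanged groups against shared controls limma called 0 genes in both in the same direction, and at an unadjusted p under 0.05 the simulated sets gave a median of 11 and at most 3121 such genes against 3356 observed. The correlation of both fold changes across genes, which are not independent replicates, was 0.339, below the simulated median of 0.598 (highest 0.965). Their covariance was 0.0248 (simulated median 0.00148, highest 0.00713). Part of the excess of the 1387 and 990 genes over the 423 and 283 of independent lists may come from the shared controls. Those expected numbers also count over all 19935 genes, dim ones included. With probe sets below the median left out, 4818 genes were called in Net and 5618 in Sap-1 shRNA cells, and 2520 in the same direction in both. Independent lists over the brighter genes alone would therefore share more than 423 and 283. With each line taken in turn as the reference, the genes called in the same direction in both other lines numbered 2377 for control, 2126 for Net shRNA and 3290 for Sap-1 shRNA cells.

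**Figure D3:**
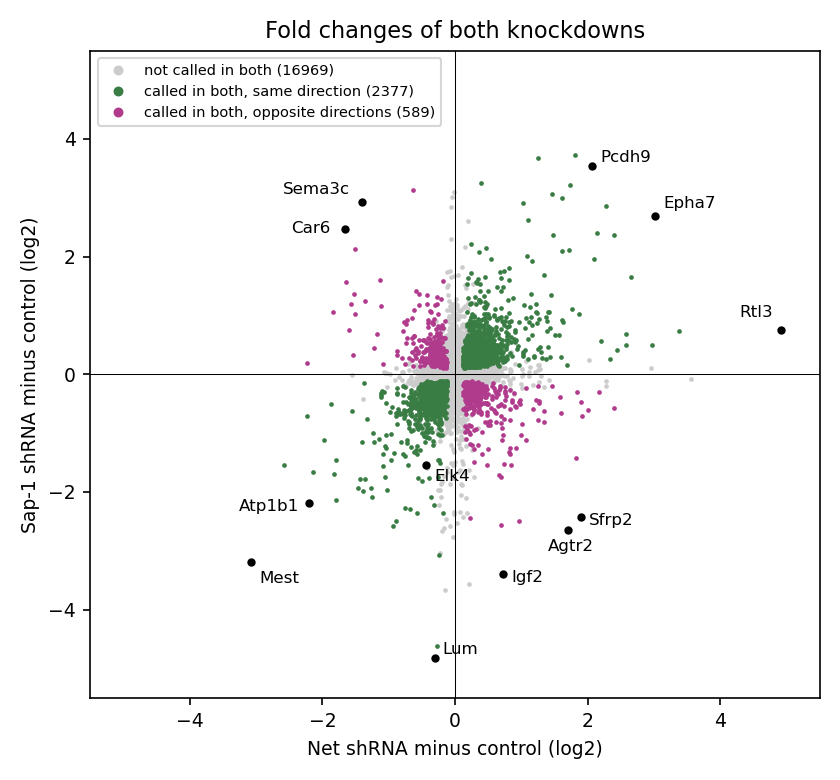
Log2 fold changes against control of the 19935 genes tested in Net shRNA (horizontal) and Sap-1 shRNA cells (vertical), each point a gene, coloured green where called in the same direction in both (2377) and purple where called in opposite directions (589). Epha7 and Pcdh9 stand high in both, Mest and Atp1b1 low in both, and Sfrp2 and Sema3c lie in opposite corners.

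Genes that neighbour each other along a chromosome shifted together, in runs and along some whole chromosomes. In Net shRNA cells the 50 neighbouring expressed genes from Tusc3 to Csgalnact1 had a median of 0.42, with 92% of them moving the same way and 39 called higher, and those from Rasa3 to Zfp703 had a median of 0.37. The run from Dhrs3 to Rpl22 lay at -0.23 (96% the same way) and that from Mob1b to Lrrc8d at -0.24. The windows from Tusc3, Rasa3 and Mob1b moved the same way in Sap-1 shRNA cells, at 0.15, 0.093 and -0.11. The window from Dhrs3 went the other way there, at 0.19. In Sap-1 shRNA cells the run from Kifap3 to Igsf8 lay at -0.34 (92% the same way, 40 called lower) and that from Cep170 to Bpnt1 at -0.29. Between the knockdowns the run from Dhrs3 to Rpl22 lay at -0.45 and that from Mgst3 to Tfb2m at 0.38. Over 1000 random gene orders the largest window median was 0.195 in Net and 0.222 in Sap-1 shRNA cells (permutation p = 0.001 for each comparison, the smallest that 1000 orders can give), and 47 and 14 of the 906 windows lay above it. In Net shRNA cells every window of the chromosome with the Tusc3 run was positive, from 0.063 to 0.418. Another chromosome was positive in every window, from 0.066 to 0.21, and a further one negative, from -0.12 to -0.04. The chromosome with the Tusc3 run was positive in every window in Sap-1 shRNA cells too, from 0.01 to 0.19. In Sap-1 shRNA cells every window of the chromosome with the run from Rap2b to Snord73b was negative, from -0.21 to -0.053. The chromosome with the run from Klf10 to Efr3a was positive in every window there, from 0.046 to 0.24. So were another chromosome, from 0.032 to 0.17, and a further one, from 0.0067 to 0.075. Many of these windows lay below the largest median of random orders in size. This window scan was chosen after seeing the data.

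**Figure D4:**
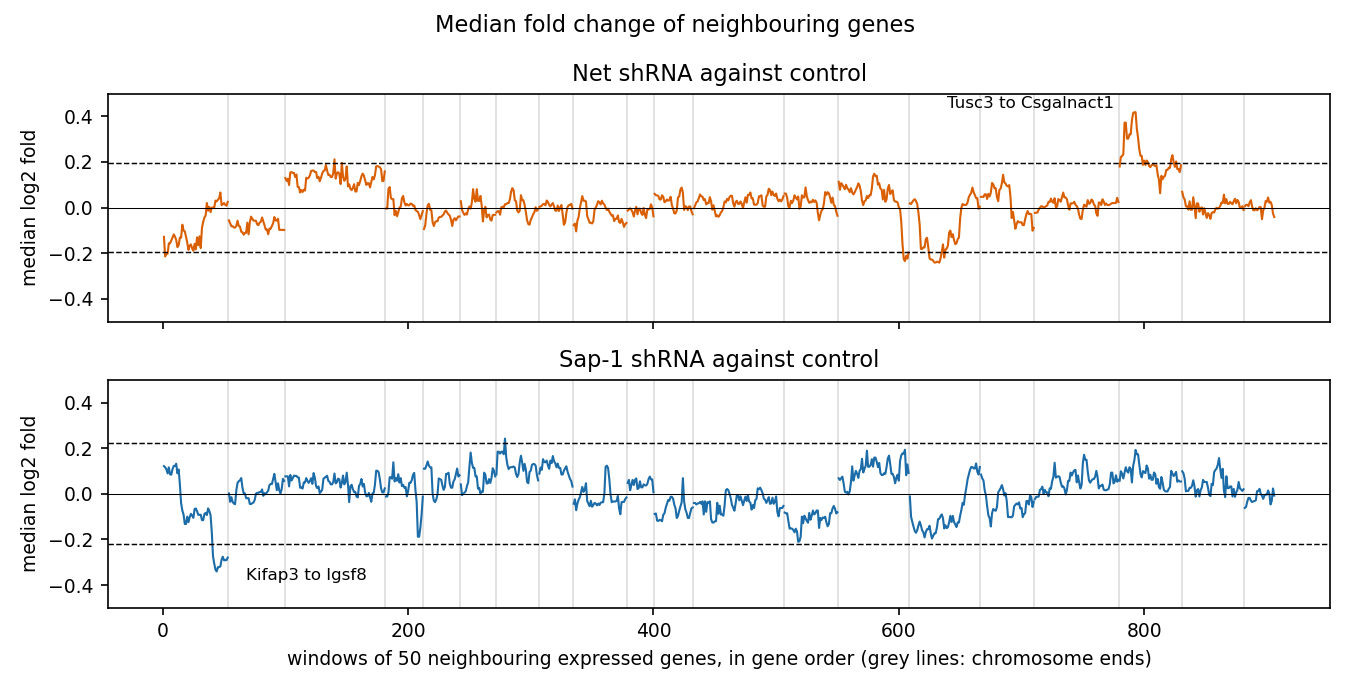
Median log2 fold change against control of windows of 50 neighbouring expressed genes in gene order, for Net shRNA (top) and Sap-1 shRNA cells (bottom), with grey lines at chromosome ends and dashed lines at the largest median of 1000 random gene orders (0.195 and 0.222). The labelled peak from Tusc3 to Csgalnact1 reaches 0.42 and the labelled trough from Kifap3 to Igsf8 reaches -0.34.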

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

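The test of how many Y-linked genes differ was chosen only after its result was seen, as was the count with each line as the reference. Each gene named in this paragraph passed limma in both knockdowns in opposite directions. The difference between the knockdowns is given as Net minus Sap-1 shRNA on the log2 scale. It passed for all 589 genes called in opposite directions, so its passing adds no further support. Higher in Net shRNA cells were Agtr2 (4.36), Sfrp2 (4.33), the collagen prolyl hydroxylase gene P3h2 (3.25), Ccl7 (2.19) and the growth factor gene Tgfb2 (2.04). Lower in Net shRNA cells were Sema3c (-4.33), Car6 (-4.14), Serpinb9b (-3.78), Cdsn (-3.63), Arhgap20 (-3.22), Cdh19 (-2.91), Eif2s3y (-2.88), Simc1 (-2.43) and Ccnd1 (-1.01).

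The Y-linked genes Eif2s3y, Kdm5d and Uty all ran in the order Net shRNA, control, Sap-1 shRNA, with Eif2s3y at 7.36, 8.88 and 10.24, Kdm5d at 6.77, 7.88 and 9.03 and Uty at 6.38, 7.52 and 9.11. Normalization is argued against, since the Eif2s3y difference moved by at most 0.024 over 3 normalizations. Female cells are argued against by Xist alone, which differed by 0.03 (SE 0.04) between the knockdown lines. Xist stood low, at 5.3 in control, 5.32 in Net shRNA and 5.3 in Sap-1 shRNA cells. No array here shows that its probe set can respond. Loss of the Y chromosome in part of the cells of a line may account for the pattern, and 75% of the 4 Y-linked genes above the median level (3 of 4) were lower in Net than in Sap-1 shRNA cells by more than 0.5. The exception was Sry, at 8.06 to 8.19 in every line, and since Sry is known as a testis gene its signal in fibroblasts need not come from its transcript, which keeps this explanation open. An effect of the shRNAs on these genes was not tested.

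The second pattern is the set of 2377 genes, led by Epha7, Mest and Atp1b1, that changed the same way in both knockdowns. Chance values of the shared control arrays are argued against as the whole cause, since the covariance of the fold changes, 0.0248, lay above the highest of 100 simulated sets, 0.00713, while the 0 genes that limma called in those sets (at most 3121 against 3356 observed at an unadjusted p under 0.05) decide nothing, since unchanged groups give few adjusted calls. A control group that stands apart from both others could give the same set. With 1 control group it cannot be told apart from a shared effect of both knockdowns. The covariance of the fold changes exceeds its simulated value by 0.0233 in either case. The control carried the empty vector, so it also differed from both others in carrying no shRNA, and that difference cannot be told apart either. A set of this size was not particular to the control as the reference, since Net shRNA cells gave 2126 genes and Sap-1 shRNA cells 3290. A shared fall of Elk4, which fell in both lines, stays open and was not tested apart from these.

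Other splits of the arrays bear on the counts. For genes, 1 of 10 splits in each comparison, the real one, gave as many as the real count. Those counts were 4714 in Net shRNA cells, 5921 in Sap-1 shRNA cells and 5480 between them. In the other splits limma called at most 0 genes, with at most 1232, 605 and 1346 at an unadjusted p under 0.05. Every other split mixed arrays of both groups, which puts their difference into the spread. Few calls would be found there whenever the groups differ, whatever the cause. For lists, 5 of 10 splits shifted as many as the 7 in Net shRNA cells (highest other 7), 1 of 10 as many as the 10 in Sap-1 shRNA cells (highest other 9) and 4 of 10 as many as the 7 between the knockdowns (highest other 8). With 10 splits the share cannot go under 0.1. For the overlap, 1 of 100 splits of the 9 arrays, the real one, reached 2377, the highest other being 982 in a split that kept the 3 arrays of 1 group as its control group. Chance can be excluded there only in the sense that the groups differ, since every drawn split that mixed the groups in its control group gave 0 with limma and the real groups with Sap-1 shRNA as the reference gave 3290.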

How the results depend on the processing

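The alternative that takes off the neighbours' median was chosen after seeing the data. At 1.5-fold the counts of genes changed dropped to 510 in Net shRNA cells, 890 in Sap-1 shRNA cells and 924 between them, because the threshold is stricter. With an estimated correlation camera shifted 0 lists in each comparison (3 at an unadjusted p under 0.05 in each), and fry called 12 between the knockdowns. Without one array at a time the counts ran from 3848 to 4766, from 5043 to 6160 and from 4770 to 5481, the fall of Elk3 in Net shRNA cells from -0.44 to -0.41, that of Elk4 in Sap-1 shRNA cells from -1.56 to -1.51, the shifted lists from 6 to 7, 9 to 10 and 7 to 8, and the overlap from 1896 to 2328. Under the other alternatives these counts stayed within 1.5 times, but the balance of higher and lower genes turned between the knockdowns from 2823 and 2657 to 2352 and 2819 with each array centred on its median, to 3266 and 3283 with every probe set, to 2925 and 2926 with quantile normalization and to 2497 and 2593 without Net replicate 2, and in Sap-1 shRNA cells to 3265 and 3576 with the neighbours' median taken off. Same-numbered arrays paired at most in part (9 pairs, r from -0.11 to 0.36, 5 above 0.1, 4 arrays matching best with their own number). The pairs of replicate 1 lay at 0.25, 0.17 and 0.36, while differently numbered pairs reached 0.3. With the replicate block the counts rose from 4714, 5921 and 5480 to 4985, 6263 and 5752. The shifted lists went from 7 to 8 in Net shRNA cells and between the knockdowns, so a partial replicate effect stays open. Of the values of single named genes, 6460 stayed on their side of the threshold, 56 lost a call and 12 gained one, and of single lists 1322 stayed, 40 lost and 24 gained one. With the neighbours' median taken off 2 signs turned, Junb in Net shRNA cells to -0.01 and Hsd17b7 between the knockdowns to -0.02, each with its call lost as the neighbours moved alike. The fall of Elk3 in Sap-1 shRNA cells lost its call without control replicate 2 (adjusted p = 0.071), without control replicate 3 (0.064) and without Sap-1 replicate 1 (0.068), while its fold stayed at -0.12 in all 3, so the change was no smaller. Dim genes are limited by background, which the table does not give.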

Other observations

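The genes in this paragraph and the next were chosen after their values were seen, and so were the tests in which the neighbours' median is taken off. Of the imprinted genes looked at, which are expressed from one parental copy, Mest and Igf2 were among the 8 largest falls named in Sap-1 shRNA cells. The noncoding RNA genes Meg3 and Rian fell, with changes of -2.22 (SE 0.12, limma adjusted p = 1.3e-07) and -1.96 (SE 0.19, adjusted p = 1.5e-05), and Peg3 fell by 1.11 (SE 0.08). Igf2r fell by 0.57, Plagl1 by 0.48, Dlk1 by 0.44 and Rtl1 by 0.41, while Dio3 lay at -0.03 (adjusted p = 0.62), Grb10 lay at -0.05 (adjusted p = 0.53) and Ndn at 0.09 (adjusted p = 0.38). Of 40 measured microRNA genes that lie between Dlk1 and Dio3, 37 were lower in Sap-1 shRNA cells and none higher, with a median of -1.30. Of all genes tested 13.9% were lower. These microRNA genes neighbour each other and do not count as independent observations.

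In Net shRNA cells the same 40 microRNA genes had a median of -0.02, with 2 lower. Meg3 lay at -0.24 (adjusted p = 0.18) and Rian at -0.26 (adjusted p = 0.42) there. Peg3 rose by 0.70 (SE 0.08), Ndn by 0.37 and Igf2r by 0.22, while Grb10 fell by 0.50 and Plagl1, as in Sap-1 shRNA cells, by 0.57. Igf2 lay at 0.72 (SE 0.27, adjusted p = 0.086).

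The third pattern is the runs of neighbouring genes, such as those from Tusc3 to Csgalnact1 in Net shRNA cells and from Kifap3 to Igsf8 in Sap-1 shRNA cells. Chance order and neighbouring copies of 1 gene family are argued against, since the highest permutation p of the 3 comparisons was 0.001 over all genes and 0.001 with 1 gene kept per symbol root, the smallest that 1000 orders can give. A gain or loss of a chromosome segment in a line stays open, since DNA was not measured, and the 92% or more of genes that moved the same way in the most shifted window of each comparison do not decide it, because the windows were ranked by their median. In Net shRNA cells Elk3 differed from the median of its neighbours by -0.35 with 1 of 50 lower, which argues against a run as the cause of its fall, while Elk4 differed by -0.28 with 5 of 50 lower, so a part of a run in its fall stays open. A shift equal to the neighbours' median does not account for most calls. With that median taken off, a share of 0.78 of the genes called in Net and 0.816 of those called in Sap-1 shRNA cells kept their call. The same step newly called 1593 and 2005 genes. A gene that moved further than its neighbours' median can keep its call, so larger effects of a run on single genes stay open. An effect of either shRNA on long runs of genes stays open as untested.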
